A study of Rattus norvegicus with 8 samples.

How the data were processed

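Liver RNA samples, 8 in all, of male Sprague Dawley rats, a common outbred laboratory strain, were hybridised to 1-colour Agilent oligonucleotide arrays, 4 from a high-fat diet and 4 from a normal diet, called control here. Per the labels' protocols, livers were snap frozen, RNA was isolated with TRIzol, and 500 ng of total RNA per sample was copied from an oligo-dT primer into Cy3-labelled cRNA. Groups and replicate numbers came from the sample titles. The labels do not say outright that each sample is a separate animal, so p-values measure the spread between these samples.

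Per the file headers, the spot intensity values were made with Agilent Feature Extraction 10.7.3.1, which subtracted background, detrended each array and replaced dim spots by a surrogate value. The authors' deposited value table holds log2 values for 46883 probes, with its scaling not given in the sources used here. Set against the scanner values of the same array after scaling to the 75th percentile of all non-control probes, each of its columns had a correlation of at least 0.999, and at least 98.47% of its values lay within 0.05. Its column medians were -3.14, -3.20, -3.16 and -3.20 for high-fat replicates 1 to 4 and -3.10, -3.21, -3.14 and -3.17 for control replicates 1 to 4. The comparison showed a log2 scale with no centring per probe and higher values for brighter spots. That table served as an alternative.

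Each array had 62976 spots, of which 58717 were not controls. They came from 46883 distinct probes under 25512 gene names. Control spots and spots flagged as outliers were left out, and no spot was saturated. The log2 processed signal of each array was set relative to the 75th percentile of the probes well above background on all 8 arrays, because only 48.0% of probes met that condition. A normalized log2 intensity of 0 is therefore the level of that percentile. Spots of a probe were averaged. The 31546 probes well above background on at least 4 arrays, counted without regard to group, were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. A gene stood for its probe with the highest mean, which gave 18595 gene names, 13376 of them with a symbol. Accessions of 23035 of the tested probes (73.0%) matched a gene of the GRCr8 RefSeq table, used for names only. Probe coordinates are those of the files, on rn4.

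Where a probe was not well above background on any array of a group, its fold is a lower bound. It sets the mean of the brighter group against the mean, per array of the dimmer group, of the higher of the probe's own value and the lowest signal among probes well above background there.

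The 34 gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the lists, and again with an estimated correlation, with fry and with an exact two-sided permutation of the mean list values. A list needed at least 5 tested members. The lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule took the 12 genes with the largest change in each direction among named genes past the threshold with no overlap between groups, up to 4 members of each list with the smallest p, and a fixed set of lipid and glucose genes. The text gives a part of these, single values of some genes are not reported here, and genes named outside the rule are said to be so.

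The tests were tried on 20 simulated data sets of 31459 independent probes with 200 changed. With each probe's own spread, 40.3% of the 2-fold and 79.6% of the 4-fold changes were recovered, and on average 6.31% of the called probes were unchanged ones. With shrunken spreads these were 36.5%, 86.7% and 4.21%. All 3 lists shifted by 0.5 were found in each simulated set, with 0.25 and 0.1 other lists called on average. The simulated probes were independent, so this says nothing of correlated genes.

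All 8 arrays lay on 1 slide, with 2 arrays of each diet in each of its 2 rows, and were scanned on 1 day. Alternatives changed the background correction (normexp with an offset of 50), the scaling, the filter on dim probes, the summary per gene, the variance model, array weights, blocks for replicate number and slide row, the threshold, and each array left out in turn. Scaling over all non-control probes and leaving out the 2 dimmest arrays were added after the data were seen.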

Results

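Transcript levels were measured in 4 liver samples of rats fed a diet with 60% fat for 12 weeks and 4 of rats fed a normal diet for the same time. The labels give the animals' weight as 180 to 200 g for both groups. When it was taken is not stated here, so it does not compare weights after the diets. The series asks which factors accompany insulin resistance brought on by a high-fat diet. Between 50.4% (control replicate 1) and 71.9% (control replicate 4) of the 46883 probes were well above background on an array, with high-fat replicate 1 at 56.4% and the other high-fat arrays at 67.1% to 71.4%. The number of arrays limits the precision. Correlations across probes were 0.970 to 0.985 between control arrays, 0.971 to 0.982 between high-fat arrays and 0.960 to 0.980 between the groups.

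In the livers of rats on the high-fat diet, the lists of fatty acid and triglyceride synthesis, cholesterol synthesis and class II antigen presentation were lower by camera at the preset correlation, with 5 of 22, 8 of 25 and 4 of 10 members past the threshold singly, among them Fasn, Elovl6, Acly and Sqle. None of the 3 passed with an estimated correlation (adjusted p = 0.16, adjusted p = 0.16 and adjusted p = 0.097 with an estimated correlation). Among single genes, Lrat, which makes retinyl esters for storage, and Akr1c1, an aldo-keto reductase, were higher. Of 18595 genes tested, 163 changed at an adjusted p under 0.05, 65 higher and 98 lower, and 118 of them by at least 2-fold. All 163 had no overlap between the groups' values, as did 11.1% of all tested genes against 2.86% by chance. Of the 31546 probes, 286 changed, 119 higher and 167 lower. A further 54 genes were called only by a probe other than the one that stood for them, and counts of genes leave these out. Of 122 called genes with several tested probes, 117 had all probes of one sign. Leaving out 1 array gave 53, 39, 28 and 73 genes without control replicates 1 to 4 and 89, 16, 47 and 28 without high-fat replicates 1 to 4, and 10 of the 163 passed in all 8 of these fits. With slide row as a block 98 genes passed, without the filter on dim probes 5, and without the 2 dimmest arrays 14.

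**Figure D1:**
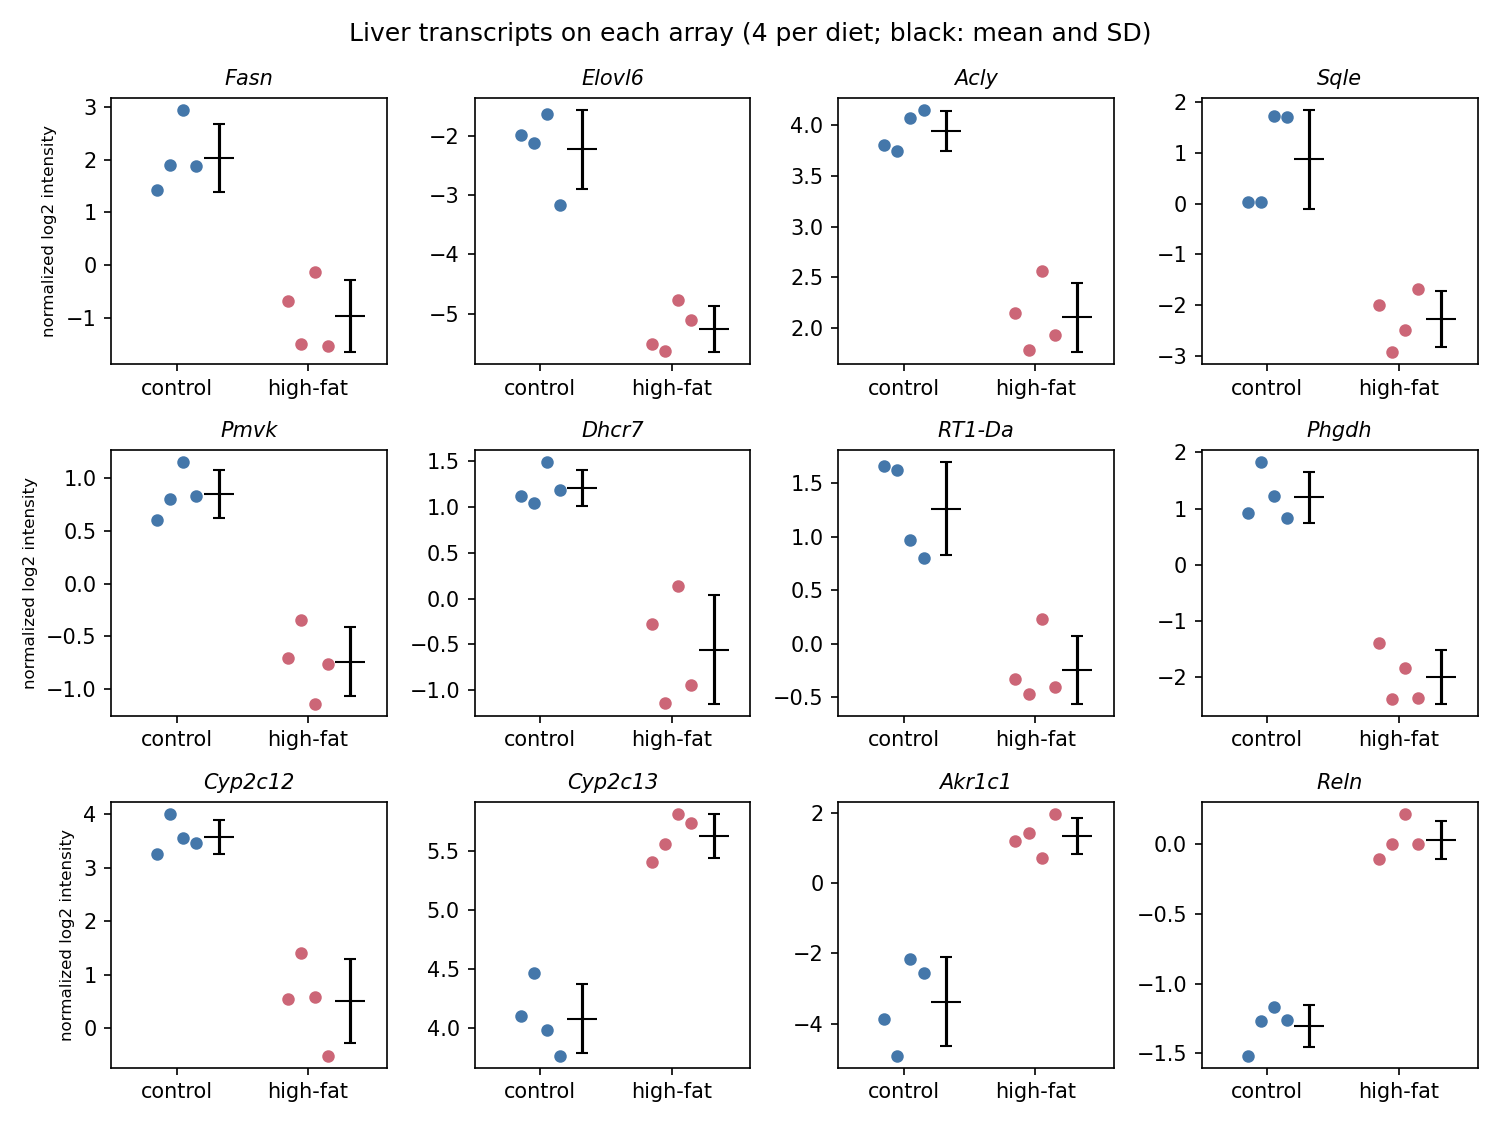
Normalized log2 intensity (vertical axis) of 12 transcripts on each of 4 control and 4 high-fat arrays, one point per array, with the mean and SD in black and a separate axis range for each gene. In each panel the groups do not overlap, as for Fasn, with a mean of 2.03 in controls and -0.96 on the high-fat diet.

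Genes of fatty acid and triglyceride synthesis were lower on the high-fat diet, with a median log2 change of -0.95 over 22 tested members. Fatty acid synthase, Fasn, fell by 2.99 on the log2 scale, from 2.03 ± 0.64 to -0.96 ± 0.68 (SD, n = 4 per group; adjusted p = 0.025 by limma). The elongase Elovl6 had a log2 change of -3.03 (adjusted p = 0.016), ATP citrate lyase Acly -1.84 (adjusted p = 0.015), Acacb, the acetyl-CoA carboxylase of the mitochondrial surface, -1.57 (adjusted p = 0.023; -1.03 after normexp) and the acetoacetyl-CoA synthetase Aacs -3.35 (adjusted p = 0.032; -1.98 after normexp). The call was lost in 10 of 20 alternatives for Aacs, 8 of 21 each for Fasn and Acacb, 4 of 21 for Elovl6 and 3 of 21 for Acly. These 5 members fell, none rose and 17 did not pass, and adjusted over the list alone 11 fell. Scd1, a desaturase, had a log2 change of -3.27 with a 95% interval from -5.77 to -0.78 (adjusted p = 0.21), and Srebf1, the transcription factor of the pathway, -0.94 (adjusted p = 0.44). Acaca was well above background on at most 3 arrays by any probe and was not tested. The list passed camera with the preset correlation (adjusted p = 3.4e-09) and not with an estimated one (adjusted p = 0.16 with an estimated correlation).

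Cholesterol synthesis was lower as well, and all 25 tested members had a negative log2 change, with a median of -1.43. Squalene epoxidase, Sqle, fell by 3.15 on the log2 scale, from 0.88 ± 0.98 to -2.27 ± 0.54 (SD, n = 4 per group; adjusted p = 0.035 by limma; call lost in 10 of 21 alternatives). Pmvk, a kinase of the mevalonate pathway, had a log2 change of -1.59 (adjusted p = 0.018), Hsd17b7 -1.73 (adjusted p = 0.036) and Dhcr7, which makes the final step to cholesterol, -1.77 (adjusted p = 0.038), the last 2 with calls lost in 11 of 21 alternatives. Of the members 8 fell and 17 did not pass, and adjusted over the list alone 17 fell. Camera gave an adjusted p of 1.1e-17 at the preset correlation, and adjusted p = 0.16 with an estimated correlation. Within the first and the second slide row the median log2 change was -0.86 and -1.74 for this list and -1.12 and -0.96 for fatty acid and triglyceride synthesis.

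Circadian clock genes and erythroid markers, the first of which follow the hour of day and the second of which mark red cells, differed between the same groups. The clock list had a median log2 change of 0.61 over 18 members (adjusted p = 0.0012 by camera, adjusted p = 0.16 with an estimated correlation), with Per2 at 0.73 (adjusted p = 0.099) and Cry1 at 1.19 (adjusted p = 0.14; 0.41 by its other probe). The erythroid list had a median of 1.08 over 8 members (adjusted p = 0.0020 by camera, adjusted p = 0.16 with an estimated correlation), with Alas2, an enzyme of heme synthesis, at 1.43 (adjusted p = 0.09; 0.36 by its other probe) and Hbb at 1.05 (adjusted p = 0.18). No single member of either list passed over all probes. Adjusted over the list alone, 3 clock and 4 erythroid genes were higher. Medians within the first and the second slide row were 0.22 and 0.82 for clock genes and 0.42 and 1.20 for erythroid markers.

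Class II antigen presentation was lower on the high-fat diet, and all 10 tested members had a negative log2 change, with a median of -1.0. RT1-Da, a class II alpha chain, fell by 1.51 on the log2 scale, from 1.27 ± 0.44 to -0.24 ± 0.32 (SD, n = 4 per group; adjusted p = 0.041 by limma). RT1-Ba had a log2 change of -1.41 (adjusted p = 0.049), RT1-DMa -0.87 (adjusted p = 0.027) and Ciita, the class II transactivator, -0.86 (adjusted p = 0.035), with -0.20 and no call by its other probe. Of 21 alternatives the call was lost in 16 for Ciita, 12 for RT1-Ba and 11 each for RT1-Da and RT1-DMa. These 4 fell and 6 did not pass, and adjusted over the list alone all 10 fell. The list had an adjusted p of 8.0e-12 by camera, and adjusted p = 0.097 with an estimated correlation. Its medians within the slide rows were -1.38 and -0.86.

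Other immune lists were lower by camera at the preset correlation, with smaller median changes. Only the macrophage list was tested against class II, and the test given below left that difference open. Interferon response genes had a median log2 change of -0.47 over 26 members (adjusted p = 2.5e-06 by camera, adjusted p = 0.40 with an estimated correlation), and 1 member fell over all probes, Bst2, with -2.17 (adjusted p = 0.041; call lost in 12 of 21 alternatives). Lymphocyte markers had a median of -0.24 (adjusted p = 0.034, and adjusted p = 0.40 with an estimated correlation), and the T cell receptor component Cd3g fell by 1.44 on the log2 scale (adjusted p = 0.042; call lost in 12 of 21 alternatives, each single left-out array among them). Macrophage and Kupffer cell markers had a median of -0.31 (adjusted p = 0.00090, and adjusted p = 0.40 with an estimated correlation) and inflammatory signalling -0.17 (adjusted p = 0.034, and adjusted p = 0.37 with an estimated correlation), with no member past the threshold in either. The call of the lymphocyte list was lost in 8 of 24 alternatives and that of inflammatory signalling in 7. Adjusted over the list alone, 7 interferon, 5 lymphocyte, 0 macrophage and 1 inflammatory gene fell. Within the first and the second slide row the macrophage median was -0.04 and -0.50, so its fall was near absent in the first. Those of interferon were -0.23 and -0.72, of lymphocyte -0.16 and -0.35 and of inflammatory genes -0.18 and -0.42. Cd207, a lectin of Langerhans cells, was at least 18.2-fold lower, being not well above background on any high-fat array (adjusted p = 0.00032), with a log2 change of -1.94, or 3.83-fold, after normexp, and the eotaxin Ccl11 had a log2 change of -4.03 (adjusted p = 0.015), and -2.11 after normexp. Ccl21, a chemokine with near-identical copies in the rat, had a log2 change of -2.40 (adjusted p = 0.016).

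**Figure D2:**
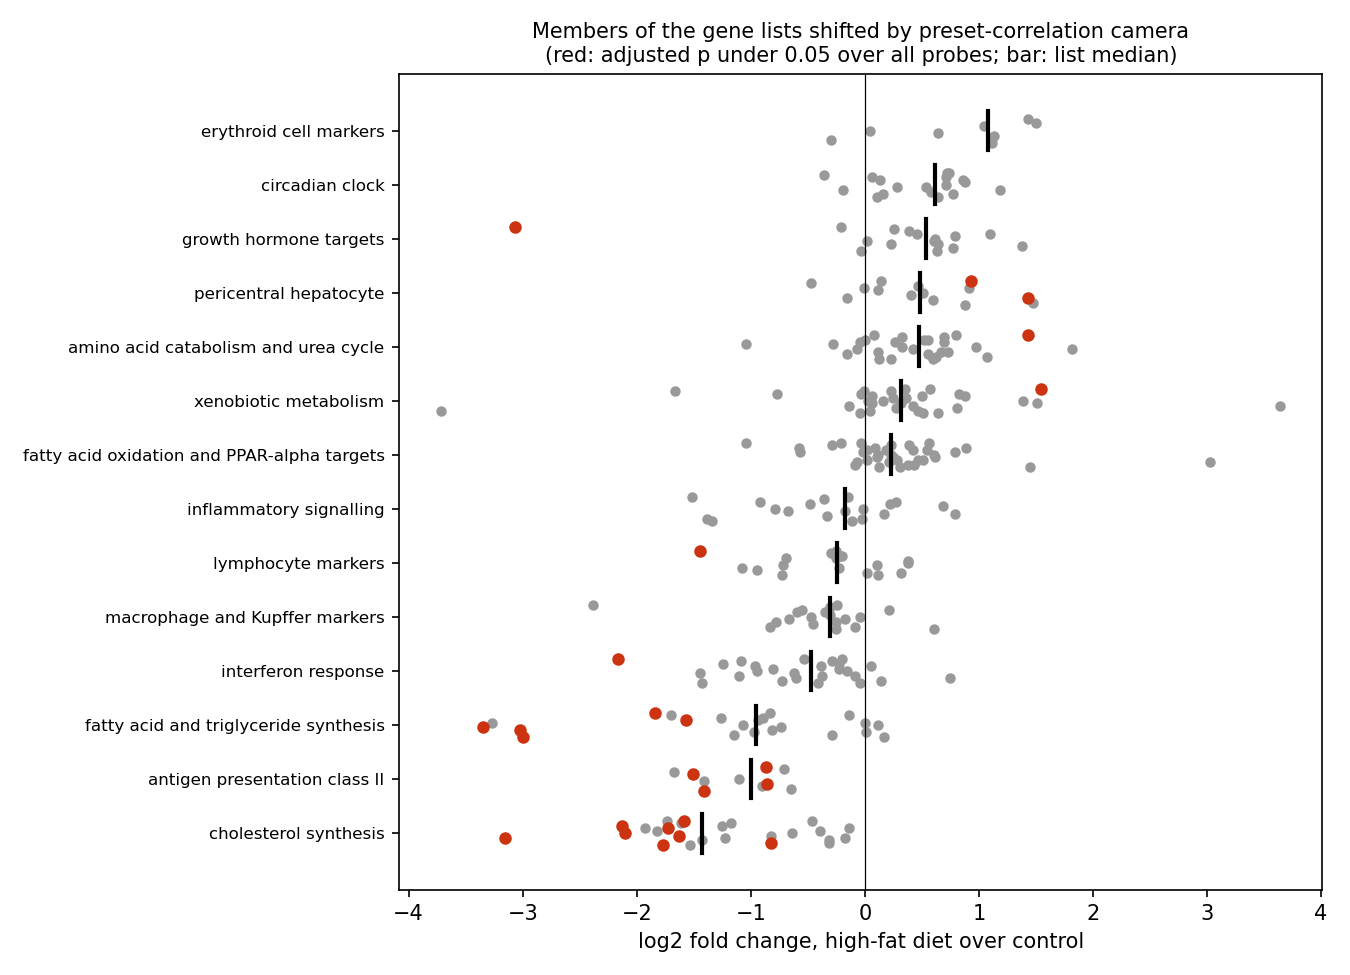
Log2 fold change of high-fat diet over control (horizontal axis) for the tested members of the 14 lists shifted by camera at the preset correlation, one point per gene, in red where the adjusted p over all probes is under 0.05, with a bar at the list median. All 25 cholesterol synthesis and all 10 class II members lie below 0, and the lone red point of the growth hormone list is Cyp2c12 at -3.07.

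Some lists of hepatocyte metabolism were higher on the high-fat diet by camera at the preset correlation, while others, given below, did not pass and those of lipid synthesis were lower. Amino acid catabolism and the urea cycle had a median log2 change of 0.47 over 28 members (adjusted p = 8.1e-06 by camera, adjusted p = 0.27 with an estimated correlation), and 1 rose over all probes, Oat, ornithine aminotransferase, with 1.43 (adjusted p = 0.049), a call lost in 16 of 21 alternatives. Pericentral hepatocyte genes had a median of 0.49 (adjusted p = 0.00036, and adjusted p = 0.19 with an estimated correlation), with Oat and the ascorbate synthesis enzyme Gulo, at 0.93 (adjusted p = 0.042; call lost in 12 of 21), past the threshold. Fatty acid oxidation and PPAR-alpha targets had a median of 0.23 (adjusted p = 0.00071, and adjusted p = 0.19 with an estimated correlation), with no single gene called, as for Acadm with 0.56 (adjusted p = 0.12), Cpt1a with 0.79 (adjusted p = 0.35) and Pdk4 with 0.02 (adjusted p = 0.99). Adjusted over the list alone, 10, 5 and 0 members were higher in these lists. In the same order, their medians within the first and the second slide row were 0.16 and 0.66, 0.39 and 0.46, and 0.11 and 0.27. The muscle form of carnitine palmitoyltransferase, Cpt1b, fell by 2.64 on the log2 scale (adjusted p = 0.020).

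Xenobiotic metabolism had a median log2 change of 0.32 over 31 members (adjusted p = 0.0016, and adjusted p = 0.19 with an estimated correlation). Cyp2c13, a male-predominant cytochrome P450, rose by 1.55, from 4.08 ± 0.29 to 5.62 ± 0.19 (SD, n = 4 per group; adjusted p = 0.016 by limma). Growth hormone targets had a median of 0.53 and a mean of 0.29 over 16 members (adjusted p = 0.0016, and adjusted p = 0.16 with an estimated correlation). The 1 member that passed had a sign opposite to the list median: Cyp2c12, a female-predominant cytochrome P450, fell by 3.07 on the log2 scale, from 3.57 ± 0.32 to 0.51 ± 0.79 (SD, n = 4 per group; adjusted p = 0.018). The list was not divided into male- and female-predominant genes, so whether this fall runs against its pattern was not tested. Adjusted over the list alone, 5 xenobiotic genes were higher and 2 lower, and 7 growth hormone targets were higher and 1 lower. Members of these P450 families share sequence, so their probes may be read by more than 1 transcript.

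Lrat, with its probe on chromosome 2 from 174636541 to 174636600 on rn4, was at least 103-fold higher on the high-fat diet by that probe, with no control array well above background by any of its probes and all 4 high-fat arrays at -1.86 ± 0.50 (SD, n = 4; adjusted p = 0.0038 by limma). Its second probe gave at least 25.8-fold (adjusted p = 0.0094), and after normexp the log2 changes of the 2 probes were 3.52 and 1.87. It belongs to the list of extracellular matrix and stellate cell genes, as do Lox, a collagen cross-linking enzyme, which was at least 18.5-fold higher (adjusted p = 0.027; log2 change of 1.76 after normexp; call lost in 10 of 20 alternatives), Mmp2, with a log2 change of 1.54 (adjusted p = 0.015), and Reln, with 1.34 (adjusted p = 0.015). These 4 members rose and 20 did not pass, and adjusted over the list alone 5 rose and 5 fell. The list as a whole did not pass (median 0.09, adjusted p = 0.10 by camera). Akr1c1 rose by 4.69 on the log2 scale (adjusted p = 0.018; call lost in 6 of 21 alternatives) and Akr1c2 by 2.65 (adjusted p = 0.032; call lost in 10 of 21), and these paralogs may share signal. The probe for the defensin Np4 was at least 17.1-fold higher (adjusted p = 0.016), while a second probe of that gene had a log2 change of 0.63, and after normexp the first had 1.75. Odz2, now named Tenm2, rose by 3.75 (adjusted p = 0.034; call lost in 10 of 20 alternatives), and had 2.07 after normexp.

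Among the genes of glucose and lipid handling chosen in advance, none of Cyp7a1, Pck1, G6pc, Insr, Irs1, Irs2, Igfbp1, Cd36, Pparg, Fgf21 and Adfp, now named Plin2, passed the threshold. The change of Insr, the insulin receptor, was 0.14 with a 95% interval from -0.28 to 0.56, that of Irs1 -0.23 (-0.79 to 0.34) and that of Irs2 0.04 (-0.83 to 0.90). Igfbp1 had a log2 change of -2.12 with an interval from -4.45 to 0.21, and Cd36, a fatty acid transporter, -1.0 (adjusted p = 0.22). The remaining lists did not pass camera. The nearest was periportal hepatocyte genes (median 0.30, adjusted p = 0.059). Acute phase proteins (0.10), cholangiocyte markers (0.10), gluconeogenesis (0.12), neutrophil markers (0.17), bile acid synthesis and transport (0.18), adipocyte markers (0.18) and lipoprotein metabolism (0.21) had the adjusted p given with each. So had cell cycle (0.29), endoplasmic reticulum stress (0.31), oxidative phosphorylation (0.31), skeletal muscle markers (0.31), the NRF2 oxidative stress response (0.43), insulin signalling (0.53), exocrine pancreas markers (0.69), glycolysis and glycogen (0.75), immediate early genes (0.82), sinusoidal endothelial markers (0.99) and lipid droplet and fatty acid uptake (0.99). Among their members Orm1, an acute phase protein, had a log2 change of -1.25 (adjusted p = 0.044; call lost in 12 of 21 alternatives), Asns, asparagine synthetase, -2.80 (adjusted p = 0.024; call lost in 8 of 21) and Fabp5 -1.72 (adjusted p = 0.027; call lost in 9 of 21).

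Of the 34 lists 14 were shifted at the preset correlation, 7 higher and 7 lower. With an estimated correlation 0 passed, and 9 passed fry, which asks whether the genes of a list move one way on balance. The exact two-sided permutation of list means cannot give a p under 0.0286 with 4 arrays against 4, and after adjustment over the lists 0 passed.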

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

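The tests of Cyp2c12 against other Cyp2c genes and female-predominant genes, and that of class II genes against macrophage markers, were chosen after the values were seen. A sample far from the other 3 of its group stood out in 5 of 214 sets of 4 values tested, those of the genes and lists reported here and of the array measures, where chance gives about 1 in 20.

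Control replicate 3 had Ccl21 at a normalized log2 intensity of -0.23, against -1.41 to -1.23 in the other controls. High-fat replicate 3 had Mmp2 at -2.0, against -2.54 to -2.52. Control replicate 4 had a mean of the lipid droplet and fatty acid uptake list of -1.11, against -0.83 to -0.81. High-fat replicate 4 had a mean of the amino acid catabolism and urea cycle list of 3.31, against 2.65 to 2.75. High-fat replicate 2 had a mean of the cholangiocyte marker list of -4.86, against -4.33 to -4.23.

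Lrat was at least 103-fold higher on the high-fat diet by its brighter probe and at least 25.8-fold by the other. More stellate cells, which hold Lrat in the liver, would raise their other markers alike, and the highest upper 95% limit of the log2 change among 14 such markers was 1.65, against lower bounds of 6.68 and 4.69 for the 2 Lrat probes, which argues against stellate cell number as the whole cause. After normexp that limit was 1.49 and the log2 changes of the 2 Lrat probes were 3.52 and 1.87, so by the dimmer probe the margin is small there. The 14 markers, chosen beforehand, leave out Lox, Mmp2 and Reln of the extracellular matrix and stellate cell list, which rose, and the interval of Lox, from 2.93 to 5.65, reaches the lower of the 2 bounds. A smaller rise stays open, since the markers had a median of 0.45 (camera p = 0.0023, and p = 0.040 with an estimated correlation), with 3 of 35 splits of the arrays giving as small a p. Higher retinoid signalling stays open: camera gave p = 0.485 for the retinoid-induced genes tested, and in the permutation of arrays 19 of 35 splits gave as small a p. The limit set beforehand, a p of 0.05 or above, was a poor one, since a missed threshold excludes nothing where members go both ways, with Stra6 at 0.41 and Tgm2 at -0.51.

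Cyp2c12, a female-predominant P450, was lower on the high-fat diet in animals all labelled male. A mislabelled female among the controls would lack Y-linked transcripts. The lowest high-fat array exceeded the lowest control array by at most 0.19 log2 for Eif2s3y and Ddx3y, which argues against such a mislabelling. No female sample was at hand to show how these probes read without a Y chromosome. Cyp2c12 itself was at 3.25 to 4.01 on all 4 control arrays, against at most 1.41 on the high-fat arrays. A single mislabelled control would therefore not account for its difference. Signal from the 7 other Cyp2c genes tested would need 1 of them to fall, and 0 had a 95% interval below 0. A fall of the female-type pattern as a whole is argued against by the other female-predominant genes, of which 1 of 5, Sult2al1, had an interval below 0. Cyp2c7 had a log2 change of 3.64 with an interval above 0 (adjusted p = 0.058 by limma) and Cyp2a1 -0.04 (-0.34 to 0.26). Prlr, at 1.65 with an interval above 0 (adjusted p = 0.25 by limma), and A1bg were dim, with control means of -6.46 and -7.72. The argument thus rests on few well-measured genes. An effect of the diet on Cyp2c12 itself stays a hypothesis.

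Class II genes were lower on the high-fat diet. A single array as the cause is argued against, since the highest adjusted p of the list was 2.1e-10 over the 8 fits that left out 1 array (camera at the preset correlation; over the alternatives tried the adjusted p ran from 1.8e-13 to 0.11). Fewer leukocytes of every kind stay open: the group difference of the class II mean less the macrophage mean was -0.69 log2, with an exact two-sided permutation p of 0.057, and these explanations cannot be told apart with 4 arrays a group. An effect of the diet on antigen presentation is equally open.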

How the results depend on the processing

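Each of the 163 genes kept its sign in every alternative in which it was tested. For fits to the same normalized values, such as those that left out 1 array, this was fixed in advance, since these genes have no overlap between the groups. The number past the threshold moved widely. Leaving out 1 array gave 16 to 89 genes, 4 to 37 higher and 12 to 63 lower, and 23 to 154 probes. Of the 163 genes 10 passed in all 8 of these fits, among them Lrat, Cd207, Phgdh, Acly, Reln and Mmp2, and 55 in none, with fewer samples as the known difference. Lists shifted ran from 13 to 16, and 12 of the 14 passed in all 8, all but lymphocyte markers and inflammatory signalling. Normexp gave 254 genes, 166 of them lower, and smaller changes for dim probes, so that the lower bounds on the fold do not hold under it: the log2 changes became 3.52 for Lrat, -1.94 for Cd207, 1.76 for Lox and 1.75 for Np4. Without the filter on dim probes 5 genes passed (1 higher, 4 lower) and 10 probes. The main p-values adjusted over the unfiltered number of probes gave 62 genes, and the unfiltered p-values adjusted over the main probes alone gave 33, so both the number of tests and the p-values had a part. With probes detected on all 8 arrays 330 genes passed (114 higher, 216 lower) and 527 probes. Trend and robust eBayes gave 333 (130 higher, 203 lower) and 543 probes. Slide row as a block gave 98 (35 higher, 63 lower) and 170 probes. Without the 2 dimmest arrays, a choice made after seeing the data, 14 passed (5 higher, 9 lower) and 25 probes. An adjusted p under 0.1 gave 506 genes (208 higher, 298 lower) and 838 probes, and an unadjusted p under 0.05 with at least 2-fold gave 469 (195 higher, 274 lower) and 828 probes. For normexp, eBayes and the slide row the cause was not tested. The deposited value table gave 160 genes. No list passed with an estimated correlation (0) or the exact permutation of list means (0), and 9 passed fry.

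The shared replicate numbers gave no clear sign of paired samples: same-numbered arrays had deviations correlating at -0.12, 0.26, 0.23 and 0.01, against -0.34 to 0.29 for arrays of different number. So few values cannot settle whether the samples were paired. With a replicate block 1 gene passed, Cd207 (0 higher, 1 lower), and 1 probe, and 14 lists did. Signal over background limited what could be measured, as 67.3% of probes could be tested.

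The splits of the 8 arrays into 4 and 4 number 35. For the count of genes chance is not excluded: 2 of them gave at least 163 genes. The other gave 188, with high-fat replicates 1 and 3 and control replicates 3 and 4 on one side. All but the first lay in the second slide row. The cause was not tested. For probes 1 split gave at least 286, the real one, and the highest other 257. For lists chance is not excluded: 2 splits gave at least 14, the highest other 18. For single lists the real split alone gave the smallest camera p for cholesterol synthesis, fatty acid and triglyceride synthesis, class II antigen presentation and circadian clock, 1 of 35 each. That is the smallest share 35 splits can give, and the exact permutation of list means gave each of these lists an adjusted p of 0.11. Chance is therefore not excluded for them. A camera p as small as that of the real split came from 2 splits for amino acid catabolism, pericentral hepatocyte genes and erythroid markers, 3 for fatty acid oxidation and growth hormone targets, 4 for xenobiotic metabolism, 5 for interferon response and 7 each for macrophage, lymphocyte and inflammatory genes. Chance is not excluded for these 10 lists either.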

Other observations

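Phgdh, Psat1, Asns, Slc1a5 and Slc38a5 below were picked after their values were seen, with no list fixed in advance, and the test on other ATF4 targets was set before the values of those targets were seen.

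Phgdh, the first enzyme of serine synthesis, with its probe on chromosome 2 from 193147943 to 193148002 on rn4, fell by 3.20 on the log2 scale on the high-fat diet, from 1.21 ± 0.45 to -1.99 ± 0.48 (SD, n = 4 per group; adjusted p = 0.0094 by limma), though its 2 probes had -3.20 and -1.19. Psat1, the next enzyme, had a log2 change of -2.57 (adjusted p = 0.039; call lost in 10 of 21 alternatives) and Asns -2.80 (adjusted p = 0.024; call lost in 8 of 21). The amino acid transporter Slc1a5 had -1.39 (adjusted p = 0.016), while another, Slc38a5, rose by 1.28 (adjusted p = 0.032). Psph, the last enzyme of the pathway, had -0.11 with a 95% interval from -0.84 to 0.61, Shmt1 -0.06 and Shmt2 -0.13.

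Phgdh, Psat1, Asns and Slc1a5 are targets of the transcription factor ATF4, and a lower amino acid response in the high-fat livers may account for them, as a hypothesis. Of 15 other ATF4 targets, Psph and Shmt2 among them, 14 had a negative log2 change, with a median of -0.26 and Mthfd2 at -1.24, and camera gave p = 0.00027 at the preset correlation and p = 0.042 with an estimated one. No single one of the 15 passed over all probes. The endoplasmic reticulum stress list, which holds Asns and Atf4 itself, did not pass (median -0.07, adjusted p = 0.31 by camera), with 11 members rising and 13 falling. Atf4 had a log2 change of -0.48 (adjusted p = 0.28 by limma). For the 15 targets as small a camera p came from 2 of 35 splits of the arrays, so chance is not excluded.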
